A study of Chlamydomonas reinhardtii with 112 samples.

How the data were processed

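The material was the green alga Chlamydomonas reinhardtii, wild type strain 4A+, a unicellular chlorophyte used to study photosynthesis and flagella. Per the labels' protocols, cells grown to mid-log phase in acetate-containing TAP medium were washed and moved to TAP without nitrogen or TAP without sulfur. The 112 samples comprise 36 RNA-seq libraries, 31 chromatin immunoprecipitation (ChIP-seq) samples of histone marks or RNA polymerase II, 10 ChIP-seq samples of the transcription factor PSR1 and 35 input libraries. The RNA libraries form 2 series, nitrogen and sulfur starvation, each with 9 times (0 hr, 10 min, 30 min and 1, 2, 6, 8, 24 and 48 hr) and 2 libraries per time, named A and B as in the file headers. The labels number the replicates and the headers letter them, and the labels do not say whether replicates were separate cultures. The p-values of expression fits below therefore measure only the spread between these libraries. The permutation and Fisher's exact tests below do not measure that spread. Per the labels' protocols, libraries were strand-specific and made from polyadenylated RNA, from 10 µg of total RNA with an Illumina kit in the nitrogen series and from 5 µg with a Kapa kit in the sulfur series. The series were therefore fitted apart, each against its own 0 hr libraries.

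The deposited RNA table holds FPKM (fragments per kilobase of transcript and 1e+06 mapped fragments), with 1 value per assembled transcript and library, per the file headers. TopHat2 2.0.8, Bowtie2 2.1.0, Cufflinks 2.1.1 and Cuffdiff (no version given) are named in the submitters' processing notes, and the design text names genome v5.3 with plastid scaffolds and Phytozome gene models. The master gene model is a Cufflinks assembly merged with Augustus u10.2 models, per the file headers. Each deposited peak list gives positions and a score per peak, and BWA 0.6.2 and MACS2 2.0.10 are named in the submitters' processing notes. The list names pair each immunoprecipitated library with an input library. Scores are on each list's own scale and were used only to rank peaks within a list. The deposited segmentations assign each 200 bp bin of the genome at 0 hr, 1 hr without nitrogen and 1 hr without sulfur to 1 of 16 states. The deposited emission table gives, per the file headers, the fraction of a state's bins that carry each of 6 marks. The tool that made the segmentation is not given in the sources used here.

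Transcript FPKM values were summed over the reference gene they belong to, or over the assembled locus where no reference gene is given. The table's 22209 transcripts and 15676 loci gave 17111 genes, of which 16735 are reference genes, 2620 carry a symbol and 2678 share an assembled locus with another gene. Fragments over a shared locus can be assigned to either neighbour, and near-identical copies such as histones exchange fragments, so values of such genes are less certain and are named as such. Gene names and descriptions were taken from the table alone. The file header pairs FPKM with transcripts, not fragment counts, so tests for counts were not run. The depth implied by the regular steps between the lowest FPKM values and by exon lengths (less 150 bases) ran from 23.4 (sulfur 30 min A) to 143 (nitrogen 1 hr B), in units of 1e+06 fragments. The sum of FPKM ran from 415385 to 545933 per library, and 11751 to 13126 genes reached 1 FPKM. The libraries of a time correlated at r = 0.874 to 0.952 across genes, which are not independent replicates. A value of 0 in 1 library beside at least 5 FPKM in the other library of the same time, called a single zero below, was found in 52 to 348 genes per library. For a gene with such a zero, each library's value is printed and no mean.

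Expression was compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend and robust, statmod 1.5.0) on log2(FPKM + 1), over genes with a mean of at least 1 FPKM at some time of the series. That left 14425 genes in the nitrogen series, 14528 in the sulfur series and 14933 in the fit of both. All 18 libraries of a series shared 1 estimate of the spread. Benjamini-Hochberg adjustment ran over all genes tested and the threshold was an adjusted p of 0.05. Fold changes are log2 values ± SE on this scale, which understates the change of genes near or below 1 FPKM. The difference between the responses was tested as an interaction, (nitrogen time minus nitrogen 0 hr) minus (sulfur time minus sulfur 0 hr), so that a kit effect equal at both times cancels. The contrasts at 1 hr, the time of the chromatin profiles, and at 48 hr, the last time, were described gene by gene, and the others by counts and lists.

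Gene lists covered nitrogen uptake and assimilation, sulfur uptake and assimilation, triacylglycerol synthesis and lipid droplets, fatty acid synthesis in the plastid, light-harvesting antenna, photoprotective antenna proteins, photosystem subunits, the Calvin cycle, chlorophyll synthesis, cytosolic and plastid ribosomal proteins, histones, DNA replication and cell cycle, gametes, intraflagellar transport and BBSome, heat shock proteins, autophagy, the proteasome, phosphate starvation and transport, acetate and glyoxylate metabolism, the carbon concentrating mechanism, starch metabolism and cell wall proteins. Lists matched whole symbols. A list with fewer than 3 members was not tested, which held for autophagy, where APG8 alone was matched, and 22 lists were tested. Lists were compared with all other genes by limma's camera, two-sided, with an inter-gene correlation preset at 0.01 and again with a correlation estimated per list, and Benjamini-Hochberg adjustment ran over the 88 tests of 22 lists and 4 contrasts. Of these, 46 passed with the preset correlation and 0 with the estimated correlation (camera, 19 at an unadjusted p under 0.05), so each camera call below is lost with the estimated correlation. The lowest adjusted p it gave was 0.0838. Counts of members are given over all genes and adjusted over the list alone. In each main contrast the named genes were the 8 symbols with the largest rise and the 8 with the largest fall among genes past the threshold, at 5 FPKM or more in either group and with the libraries of both times apart, up to 4 members per list by absolute change, and PSR1, NIT1, SLT2, ARS2 and LHCSR1 in any case. NRR1, DGTT1, MLDP1, SNRK2.2 and RBCS2 were also to be named and are not among the table's symbols. At most 2 genes without a symbol were named per direction.

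A promoter peak was a peak overlapping the window of 500 bp on either side of the transcription start by at least 1 bp. A gene gained H3K4me3 when a promoter peak was in both 1 hr lists and neither 0 hr list, and lost it in the reverse case. No test was run on these counts, since an exact permutation of 2 libraries against 2 cannot reach 0.05, and the crossed splits of the 4 libraries are given beside the counts. Peak lists were compared by the Jaccard index, the base pairs shared over the base pairs covered by either list. Shares of genes carry Wilson 95% intervals, which cover the error of counting genes and not the spread between libraries. The peak lists give no read depth. Genes with and without a mark were compared at 0 hr by a permutation test over genes (100000 resamples, two-sided), and expression changes of genes whose mark or state changed were compared with genes that kept theirs by permutation within 10 bins of 0 hr expression. The smallest p these permutations can give is 1e-05, and genes are not replicates. The differences printed are beyond the permuted mean. A promoter state was a state with an H3K4me3 emission of at least 0.5. A PSR1-bound gene had a promoter peak in both deposited files of a sample and with both antibodies at the same condition and time. Bound genes were compared with genes that rose or fell at that time by Fisher's exact test, two-sided, adjusted over 10 tests. Up to 10 bound genes and up to 8 genes with changed H3K4me3 were named. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

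The steps were tested on simulated data. Among 14425 genes simulated on the nitrogen 1 hr contrast, 62% of 100 genes changed by 1 log2 unit and 84% of 100 changed by 2 were recovered, and 15 unchanged genes were called. On the sulfur 1 hr contrast (14528 genes) these were 62%, 94% and 20. Each simulation changed only 200 genes, all with a mean log2(FPKM + 1) over 2 at 0 hr. Residuals were drawn gene by gene, without a shift of a whole library. The real contrasts called 8091 and 3692 genes, so recovery and false calls there may differ from these values. Promoter windows found 1000 of 1000 simulated peaks and 0 others. The permutation within bins passed 0.05 in 5% of 200 runs without an effect and in 100% of 50 runs with one, and Fisher's test in 2.6% of 500 random sets.

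Groups, tests, lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. These alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, fits on the libraries of the compared times alone, a replicate block by column letter, leaving out each library, a 1000 bp window, a 200 bp overlap, the upper 50% of each peak list by score, an emission of 0.8, any promoter state within 500 bp, either PSR1 file, 1 antibody, and peaks over the gene body. Alternatives chosen after seeing the data set single zeros to missing, used loci or transcripts as units, counted list members after quantile normalization, took as the PSR1 background genes with an H3K4me3 promoter peak at 0 hr, and compared the 0 hr H3K9me3 list with H3K36me3 lists. The letters A and B did not pair libraries across times. The median correlation of replicate differences sharing letters was 0.00788 in the nitrogen series and 0.00446 in the sulfur series, so the block is an alternative only. Planned tests on counts could not be run on FPKM.

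Input libraries have no processed file of their own and were not used here, and neither was the table of transitions between states. The labels are inconsistent in places. The time label of PSR1 samples reads 0 hr while their titles give starvation times, the H3K4me2 sample is titled with another mark, and the peak names in the 0 hr H3K9me3 list carry the name H3K36me3. Titles and list names were followed except for H3K4me2, where the list name was used. No PSR1 library without starvation was used here, so binding has no 0 hr comparison.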

Results

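RNA was measured at 9 times in each of 2 starvation series of Chlamydomonas reinhardtii 4A+, 1 without nitrogen and 1 without sulfur, with 2 libraries per time (36 in all). Chromatin was profiled as 31 samples of 6 histone marks and RNA polymerase II, and binding of PSR1, a Myb-like transcription factor known from phosphorus starvation, as 10 samples made with 2 antibodies. The implied depth of the RNA libraries ran from 23.4 to 143 (in units of 1e+06 fragments), and peak lists give no depth. Fold changes are log2 values ± SE from limma on log2(FPKM + 1) with n = 2 libraries per time, and FPKM values are given as libraries A and B. Transfer to starvation medium included washing, and no series washed into complete medium is used here, so each change below includes that of the transfer.

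The transcriptome series asked how gene expression changes over starvation. Without nitrogen, 1983 genes rose and 2238 fell by 10 min, 4652 rose and 3012 fell by 30 min, 5607 rose and 2484 fell by 1 hr, and 4887 rose and 2885 fell at 48 hr (limma, Benjamini-Hochberg, 14425 genes). Without sulfur, 1398 rose and 2893 fell by 10 min, 1957 rose and 1735 fell by 1 hr, and 5145 rose and 3623 fell at 48 hr (14528 genes). Changes of at least 2-fold at 1 hr numbered 2464 up and 1365 down without nitrogen, against 377 up and 415 down without sulfur. The share of called genes that rose depended on scaling. The median gene changed by 0.30 at nitrogen 1 hr and 0.24 at 48 hr, and quantile normalization moved these to 0.07 and −0.00 and the called genes to 3972 up and 3275 down at 1 hr and 3497 up and 3938 down at 48 hr. At sulfur 48 hr the median moved from 0.15 to −0.05 and the calls to 4187 up and 4607 down.

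**Figure D1:**
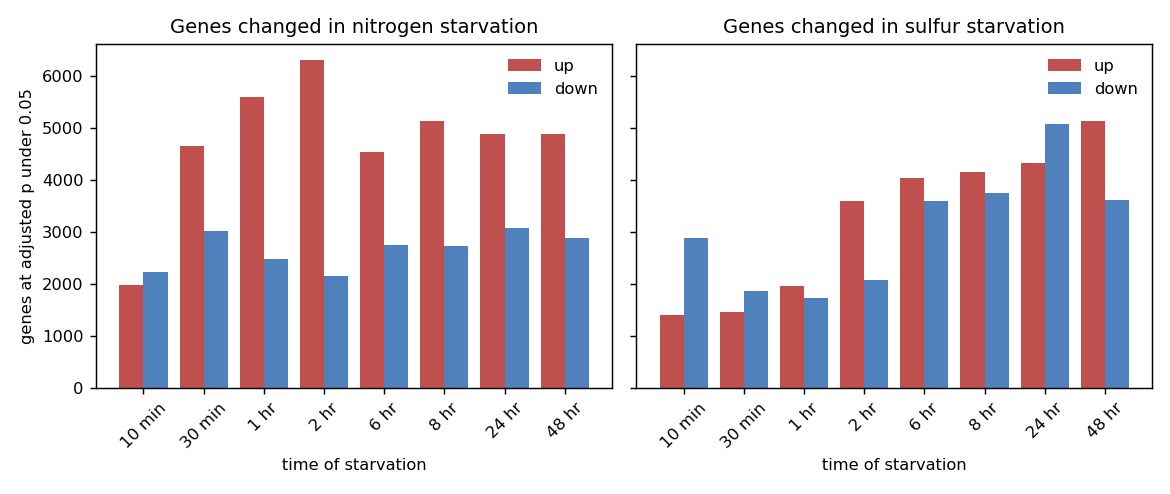
Numbers of genes (y) that rose (red) or fell (blue) against 0 hr at each time (x) of nitrogen (left) and sulfur starvation (right), limma adjusted p under 0.05. At 1 hr, 5607 genes rose without nitrogen and 1957 without sulfur.

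After 1 hr without nitrogen, genes that take up and release nitrogen compounds were among those that rose most. The ammonium transporter gene AMT4 (Cre13.g569850) rose by 9.61 ± 0.73 (adjusted p = 1.16e-06), from 0.411 and 0.056 to 908 and 998 FPKM, and AMT5 by 5.88 ± 0.31. NII1, the nitrite reductase, rose by 6.19 ± 0.13 (adjusted p = 2.46e-10). UOX1, the urate oxidase, rose by 6.27 ± 0.23, AMX2, a copper amine oxidase, by 6.99 ± 0.18 and XUV1, a xanthine and uracil permease, by 5.82 ± 0.46. NIT1, the nitrate reductase, was listed at 0 in both 0 hr libraries and at 3.97 and 4.35 FPKM at 1 hr. NSG13, described as expressed in nitrogen-starved gametogenesis, rose by 6.20 ± 0.40. Of 26 genes of nitrogen uptake and assimilation, 18 rose and 4 fell (18 and 4 adjusted over the list alone, median 1.99; camera adjusted p = 0.0141), with adjusted p = 0.279 with an estimated correlation. Of genes without a symbol, g2927 rose by 6.93 ± 0.22, from 0.843 and 0.513 to 188 and 219 FPKM, and Cre13.g603550 fell by 6.44 ± 0.37.

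Genes of the plastid's protein synthesis and photosynthesis fell in the same hour. Of 33 plastid ribosomal protein genes 30 fell (31 adjusted over the list alone, median −2.99; camera adjusted p = 2.76e-23, and adjusted p = 0.0838 with an estimated correlation), among them PSRP1 (Cre05.g237450) by −4.56 ± 0.14, from 549 and 417 to 18.8 and 19.8 FPKM, and PRPS21 by −3.98 ± 0.12. PRPL15 went from 345 and 345 FPKM to 0 in both libraries. Of 14 photosystem subunit genes 11 fell and 1 rose (12 and 2 adjusted over the list alone, median −1.50; camera adjusted p = 1.30e-06, 0.132 as adjusted p with an estimated correlation). They include PSBP1 and PSBO of the oxygen-evolving complex, which fell by 3.53 ± 0.29 and 3.18 ± 0.17. Of 12 light-harvesting antenna genes, whose products carry chlorophyll, 10 fell and 1 rose (10 and 2 adjusted over the list alone, median −1.49; camera adjusted p = 2.57e-05, 0.111 as adjusted p with an estimated correlation). LHCB4 fell by 3.33 ± 0.11 (adjusted p = 2.85e-09) and LHCA4 by 2.97 ± 0.13. Of 17 genes of chlorophyll synthesis 10 fell and 2 rose (10 and 3 adjusted over the list alone, median −1.35; camera adjusted p = 2.75e-05, 0.250 as adjusted p with an estimated correlation). GSA1, which makes the precursor aminolevulinate, fell by 3.95 ± 0.22, and CHLI1, a magnesium chelatase subunit, by 3.70 ± 0.18.

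Genes of chaperones, replication and lipid synthesis also changed at nitrogen 1 hr. CBF5, annotated as a centromere and microtubule binding protein, fell by 5.68 ± 0.14 (adjusted p = 6.27e-10) and PYR2, aspartate carbamoyltransferase of pyrimidine synthesis, by 4.98 ± 0.12. Of 20 heat shock protein genes 10 fell and 4 rose (10 and 4 adjusted over the list alone, median −1.21; camera adjusted p = 4.27e-04, 0.245 as adjusted p with an estimated correlation). HSP90A fell by 3.07 ± 0.17 and HSP70A by 3.05 ± 0.19, while HSP22E, a small heat shock protein, rose by 2.65 ± 0.22. Of 31 genes of DNA replication and cell cycle 22 rose (23 adjusted over the list alone, median 0.73; camera adjusted p = 0.00495, 0.442 as adjusted p with an estimated correlation), among them E2F1, a cell cycle transcription factor. Only 8 of 33 matched histone genes, which have near-identical copies, passed the filter. Of these 8 histone genes 5 fell (6 adjusted over the list alone, median −0.76; camera adjusted p = 0.0163, 0.442 as adjusted p with an estimated correlation), HTB37 by 1.32 ± 0.22. Of 12 genes of fatty acid synthesis 6 fell and 3 rose (6 and 3 adjusted over the list alone, median −0.97, or −0.58 with quantile normalization; camera adjusted p = 0.0330, 0.262 as adjusted p with an estimated correlation). BCC2, the biotin carrier of acetyl-CoA carboxylase, fell by 1.62 ± 0.14, and the riser PDC3 is annotated as a pyruvate decarboxylase, an enzyme of fermentation.

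The other lists did not pass camera at nitrogen 1 hr. They are cytosolic ribosomal proteins (median −0.07, adjusted p = 0.0564), intraflagellar transport and BBSome (0.46, 0.0611), sulfur uptake and assimilation (0.79, 0.0693), the carbon concentrating mechanism (6 of 10 up, adjusted p = 0.0845), the Calvin cycle (−0.82, 0.106) and the proteasome (0.35, 0.113). The rest had larger adjusted p. With quantile normalization the medians of intraflagellar transport and the Calvin cycle were 0.28 and −0.37. Among their members FLA10, the kinesin-2 motor of flagella, rose by 1.07 ± 0.08, SAT1, serine acetyltransferase of cysteine synthesis, by 1.76 ± 0.13, RCA1, rubisco activase, by 2.43 ± 0.11 and SBE3, a starch branching enzyme, by 3.23 ± 0.33. CAH1, the periplasmic carbonic anhydrase, rose by 5.76 ± 0.22 (adjusted p = 6.53e-09), from 0.187 and 0.125 to 53.0 and 71.8 FPKM. LCI8 of the same list rose by 3.34 ± 0.53 but is annotated as an enzyme of arginine synthesis and shares a locus. PSR1 (Cre12.g495100) rose by 2.91 ± 0.14 (adjusted p = 2.54e-08; to 24.4 and 25.1 FPKM), PHO1, an alkaline phosphatase, by 2.41 ± 0.12, ELI4, an early light-inducible protein, by 3.91 ± 0.13, and APG8, the ubiquitin-like protein of autophagosomes, by 3.57 ± 0.16. Cell wall proteins had a median of 0.20 and a mean of 0.10 while the test pointed down (adjusted p = 0.348). The medians of acetate metabolism, cytosolic ribosomal proteins and gametes changed sign with quantile normalization (to 0.10, 0.03 and −0.03). ARS2, a periplasmic arylsulfatase, rose by 1.27 ± 0.11, and LHCSR1, a stress-related antenna protein (0.42 ± 0.20; 0.89 with a pseudocount of 0.1, where adjusted p = 0.0217), and SLT2 (1.14 and 0 FPKM before, 0 and 3.79 after) did not pass.

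Several of the largest falls at nitrogen 1 hr had a value of 0 in library B alone. LHCA3 was listed at 1459 and 1589 FPKM at 0 hr and at 578 and 0 at 1 hr, MES1, a methionine synthase, at 359 and 234 and then 34.2 and 0, RBCS1, the rubisco small subunit, at 259 and 236 and then 34.2 and 0, and PRPL10 at 276 and 301 and then 50.9 and 0. The call of PRPL10 was lost without 1 hr library B (fitted change −2.48), with a pseudocount of 0.1, no filter, quantile normalization and a replicate block, those of LHCA3 and PRPL10 without either 0 hr library, and those of all 4 with the 2 times alone. Library B carries 348 such zeros, and 49.4% of these genes share an assembled locus against 11.8% of others, but LHCA3, MES1, RBCS1 and PRPL10 do not. COPE1, a vesicle coat subunit in a shared locus, was listed at 0 in both libraries.

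At 48 hr without nitrogen, LAO1, AMT4 and XUV1 were among the genes with the largest rises, and cell wall, replication and photosynthesis genes had fallen. LAO1, the periplasmic L-amino acid oxidase, was listed at 0 and 0.068 FPKM at 0 hr and at 575 and 641 at 48 hr. GLN3, a glutamine synthetase, rose by 7.10 ± 0.30 (adjusted p = 1.17e-08), AMT4 by 8.88 ± 0.73, and the permeases XUV1, XUV2 and XUV6 by 8.43 ± 0.46, 6.62 ± 0.20 and 6.35 ± 0.12. GPD2, a glycerol-3-phosphate dehydrogenase in a shared locus, rose by 6.38 (adjusted p = 0.00277). LHCBM7, an antenna gene, was listed at 0 at nitrogen 0 hr and at 355 and 320 FPKM at 48 hr (8.40 ± 2.25). It fell at sulfur 48 hr (−5.20 ± 0.14) and so was above 0 at sulfur 0 hr, which leaves its nitrogen 0 hr zeros uncertain. Nitrogen uptake and assimilation had 18 of 26 genes up and 2 down (18 and 2 adjusted over the list alone, median 1.78; camera adjusted p = 9.58e-05, 0.132 as adjusted p with an estimated correlation). THI4, of thiamine synthesis, fell by 9.11 ± 0.42 (1349 and 1661 to 1.18 and 2.36 FPKM), and RBD2, a rubredoxin, by 6.28 ± 0.11. FAP212, a flagellar protein in a shared locus, went from 121 and 117 FPKM to 0 in both libraries. Of 16 cell wall protein genes 8 fell and 1 rose (8 and 1 adjusted over the list alone, median −2.79; camera adjusted p = 7.31e-05, 0.111 as adjusted p with an estimated correlation). PHC18, PHC15 and PHC1, which encode pherophorins, fell by 8.57 ± 0.32, 7.80 ± 0.14 and 6.46 ± 0.36.

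Photosynthesis and the plastid ribosome stayed low at nitrogen 48 hr. LHCA5 of the photosystem I antenna fell by 5.80 ± 0.13 (1186 and 1240 to 21.7 and 19.9 FPKM), LHCB5 of photosystem II by 5.44 ± 0.10 and PSBX, a small photosystem II subunit, by 5.09 ± 0.10 (adjusted p = 6.15e-11). Of 14 photosystem genes 11 fell and 1 rose (11 and 1 adjusted over the list alone, median −3.18; camera adjusted p = 1.77e-08, 0.111 as adjusted p with an estimated correlation). Of 12 antenna genes 9 fell and 2 rose (9 and 2 adjusted over the list alone, median −4.03; camera adjusted p = 8.94e-07, 0.0838 as adjusted p with an estimated correlation). Of 33 plastid ribosomal protein genes 28 fell (28 adjusted over the list alone, median −1.87; camera adjusted p = 1.88e-17, 0.0838 as adjusted p with an estimated correlation), PSRP1 by 3.04 ± 0.14. PRPL7 went from 1016 and 1063 FPKM to 0 and 74.2, a call lost when only the libraries of the 2 times were fitted. Of 11 Calvin cycle genes 7 fell and 1 rose (8 and 2 adjusted over the list alone, median −2.20; camera adjusted p = 0.00138, 0.166 as adjusted p with an estimated correlation), among them PRK1, phosphoribulokinase, by 4.24 ± 0.55. Of 17 chlorophyll synthesis genes 8 fell and 2 rose (8 and 2 adjusted over the list alone, median −0.38, or −0.69 with quantile normalization and −0.93 with single zeros set to missing; camera adjusted p = 0.0111, 0.442 as adjusted p with an estimated correlation). CHLI1 fell by 2.23 ± 0.18.

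Replication and cell cycle genes, which had risen at 1 hr, had fallen at nitrogen 48 hr. Of 31 replication and cell cycle genes 22 fell and 2 rose (22 and 2 adjusted over the list alone, median −1.08; camera adjusted p = 1.16e-08, 0.162 as adjusted p with an estimated correlation). RIR2, a ribonucleotide reductase subunit, fell by 4.18 ± 0.18, CDKB1, a cell cycle kinase, by 4.08 ± 0.17 and MCM2, of the replicative helicase, by 3.99 ± 0.20. Of 26 intraflagellar transport genes 14 fell and 3 rose (15 and 4 adjusted over the list alone, median −0.58; camera adjusted p = 3.55e-04, 0.206 as adjusted p with an estimated correlation), IFT25 by 1.78 ± 0.09. Of 12 fatty acid synthesis genes 7 fell and 3 rose (8 and 3 adjusted over the list alone, median −0.99; camera adjusted p = 7.81e-04, 0.129 as adjusted p with an estimated correlation), BCC2 by 3.47 ± 0.14 and ACP2, an acyl carrier protein, by 2.75 ± 0.08. Of 13 acetate and glyoxylate genes 6 fell and 2 rose (6 and 2 adjusted over the list alone, median −0.40, or −0.09 with quantile normalization; camera adjusted p = 0.0448, 0.443 as adjusted p with an estimated correlation), ICL1, isocitrate lyase, by 2.49 ± 0.16. Of 8 histone genes 4 fell (4 adjusted over the list alone, median −0.79; camera adjusted p = 0.0141, 0.442 as adjusted p with an estimated correlation). Of 37 cytosolic ribosomal protein genes 23 rose (24 adjusted over the list alone, median 0.53; camera adjusted p = 0.0145, 0.458 as adjusted p with an estimated correlation), RPL4 by 1.29 ± 0.09, but with quantile normalization only 8 rose, 1 fell and the median was 0.02.

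Lists that did not pass at nitrogen 48 hr still held large single changes. FUS1, a glycoprotein of the gamete plasma membrane, rose by 2.36 ± 0.25 and HAP2, a gamete-specific protein, by 1.52 ± 0.10. GAS28 of the same list, annotated as a stress-induced hydroxyproline-rich glycoprotein, fell by 5.40 ± 0.15. In triacylglycerol synthesis (median 1.67; adjusted p = 0.348) GPD4, a glycerol-3-phosphate dehydrogenase, rose by 1.67 ± 0.23, and HSP22E rose by 3.96 ± 0.22. APG8 stayed up by 2.94 ± 0.16, ARS2 by 0.94 ± 0.11 and ELI4 by 3.69 ± 0.13, while PTA3, a phosphate symporter, fell by 1.94 ± 0.18. PSR1 did not pass (−0.11 ± 0.14, adjusted p = 0.514) but was lower with quantile normalization (−0.49, adjusted p = 0.00189). The heat shock list had a median of 0.06 and a mean of 0.30 while the test pointed down (adjusted p = 0.565), and quantile normalization moved the median to −0.15. NIT1 was listed at 2.03 and 2.78 FPKM, against 0 at 0 hr. SLT2 was listed at 1.14 and 0 FPKM at 0 hr and at 0 in both libraries at 48 hr. LHCSR1 did not pass (−0.51 ± 0.20, adjusted p = 0.0565), but passed as lower with a pseudocount of 0.1 (−1.95, adjusted p = 1.78e-04), quantile normalization (0.0290), the 2 times alone (0.0204) and single zeros set to missing (0.0491).

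After 1 hr without sulfur, genes that release and take up sulfate were among those that rose most, beside the putative haloperoxidase gene Cre13.g585500 (8.93 ± 0.21). ARS1 (Cre16.g671400) and ARS2, periplasmic arylsulfatases, rose by 8.41 ± 1.26 (adjusted p = 0.00103; 0.486 and 0.527 to 523 and 497 FPKM) and 6.80 ± 0.20 (adjusted p = 3.71e-09). SUL2, a sulfate transporter, rose by 5.51 ± 0.29, and SQD2, of sulfolipid synthesis, by 2.64 ± 0.14. Of 20 genes of sulfur uptake and assimilation 10 rose and 3 fell (11 and 3 adjusted over the list alone, median 2.25; camera adjusted p = 2.01e-05, 0.162 as adjusted p with an estimated correlation). The faller SLT3, annotated as a sodium and sulfate co-transporter in a shared locus, fell by 4.36 ± 0.53 (31.5 and 52.5 to 1.18 and 0.895 FPKM). LHCBM9, an antenna gene in a shared locus, rose by 7.15 ± 1.41 (adjusted p = 0.00467), to 691 and 768 FPKM. ECP88, an extracellular polypeptide, rose by 4.29 ± 0.17 and RDP4, with a rhodanese domain, by 4.23 ± 0.13. HYDEF, which assembles the iron hydrogenase, fell (adjusted p = 4.05e-06), and MSD2, a manganese superoxide dismutase in a shared locus, went from 101 and 111 FPKM to 0 in both libraries. PHC5, a pherophorin, went from 229 and 249 FPKM to 56.6 and 0, a call lost without 1 hr library B (fitted change −2.06), without either 0 hr library (−5.04 and −4.92), with a pseudocount of 0.1, with the 2 times alone and with single zeros set to missing (adjusted p = 0.0530 to 0.245). CAH1 fell by 2.56 ± 0.48 (924 and 1887 to 280 and 178 FPKM), a call lost when only the 2 times were fitted.

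Other groups moved less at sulfur 1 hr. Of 32 replication genes 23 rose (26 adjusted over the list alone, median 0.88; camera adjusted p = 1.02e-08, 0.245 as adjusted p with an estimated correlation), MCM2 by 1.57 ± 0.30 and ORC4, of the origin recognition complex, by 1.35 ± 0.26. Of 17 chlorophyll synthesis genes 11 rose (11 adjusted over the list alone, median 0.62; camera adjusted p = 1.46e-04, 0.279 as adjusted p with an estimated correlation), GUN4, a tetrapyrrole-binding protein, by 1.35 ± 0.24 and GSA1 by 1.18 ± 0.25. Of 26 intraflagellar transport genes 8 fell (8 adjusted over the list alone, median −0.45; camera adjusted p = 4.67e-05, 0.367 as adjusted p with an estimated correlation), KAP1, of the kinesin-2 complex, by 0.87 ± 0.11. Of 33 plastid ribosomal protein genes 5 fell (2 adjusted over the list alone, median −0.24; camera adjusted p = 2.35e-04, 0.442 as adjusted p with an estimated correlation), PSRP1 by 2.07 ± 0.15. Of 21 proteasome genes 6 rose (6 adjusted over the list alone, median 0.27; camera adjusted p = 0.00362, 0.442 as adjusted p with an estimated correlation) and 2 with quantile normalization (median 0.14), RPN1, in a shared locus, by 0.75 ± 0.14. Of 17 cell wall genes 3 fell (3 adjusted over the list alone, median −0.50; camera adjusted p = 0.0141, 0.318 as adjusted p with an estimated correlation), VSP4 among them. Of 13 acetate genes 4 fell and 1 rose (6 and 1 adjusted over the list alone, median −0.39; camera adjusted p = 0.0330, 0.442 as adjusted p with an estimated correlation), ACK1, acetate kinase, by 1.96 ± 0.19. The antenna, photosystem and cytosolic ribosomal lists had medians of −0.11, −0.09 and −0.09 and means of 0.48, 0.07 and 0.16, and none passed. With quantile normalization the medians of the last 2 turned to 0.02 and 0.04, and that of fatty acid synthesis from 0.04 to −0.05. PSR1 did not change (0.33 ± 0.36, adjusted p = 0.564). LHCSR1 was listed at 0.167 and 0.210 FPKM at 0 hr and at 1.72 and 0.791 at 1 hr. SLT2 was listed at 0 and 2.18 FPKM and then at 0 in both libraries, and NIT1 was below the filter. The count of genes that rose at sulfur 1 hr moved with the setting: 1957 in the full series, 979 with the 2 times alone, 989 without 1 hr library A and 1124 without 0 hr library B.

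At 48 hr without sulfur, small heat shock proteins and sulfur genes were high and photosynthesis genes were among the largest falls. HSP22C, HSP22E and HSP22F rose by 8.41 ± 0.27, 8.20 ± 0.25 (6.66 and 11.3 to 2883 and 2842 FPKM) and 7.48 ± 0.20. ECP88 and ECP76, extracellular polypeptides, rose by 7.87 ± 0.17 and 7.67 ± 0.17, NSG13 by 7.95 ± 0.24, and the haloperoxidase-like gene Cre03.g177250 by 9.21 ± 0.25. LHCSR1 rose by 6.17 ± 0.33 (adjusted p = 3.75e-08) and APG8 by 4.07 ± 0.15. CAH1 fell by 10.00 ± 0.48 (adjusted p = 1.78e-08), to 0.196 and 0.385 FPKM, and LCI3 went from 671 and 713 FPKM to 0 in both libraries. Of 20 sulfur genes 12 rose and 2 fell (12 and 2 adjusted over the list alone, median 1.51; camera adjusted p = 0.00714, 0.358 as adjusted p with an estimated correlation), ARS2 by 5.63 ± 0.20. Of 8 photoprotective antenna genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 2.03; camera adjusted p = 0.0292, 0.442 as adjusted p with an estimated correlation), ELI4 by 3.69 ± 0.28. Of 15 histone genes 10 rose and 2 fell (10 and 2 adjusted over the list alone, median 1.86; camera adjusted p = 0.0131, 0.245 as adjusted p with an estimated correlation), HTA37, an H2A gene, by 2.80 ± 0.25. Of 33 matched histone genes only these 15 passed the filter in the sulfur series and 8 in the nitrogen series, so the series do not test the same set. Of 21 proteasome genes 13 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.80; camera adjusted p = 0.00713, 0.454 as adjusted p with an estimated correlation), POA6 by 1.42 ± 0.09.

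Plastid and carbon genes had fallen at sulfur 48 hr. Of 33 plastid ribosomal protein genes 32 fell (32 adjusted over the list alone; mean −1.62; camera adjusted p = 3.43e-14, 0.162 as adjusted p with an estimated correlation), PSRP1 by 2.79 ± 0.15. Of 14 photosystem genes 13 fell and 1 rose (13 and 1 adjusted over the list alone, median −4.15; camera adjusted p = 5.04e-09, 0.132 as adjusted p with an estimated correlation), PSAH of photosystem I by 5.71 ± 0.10. Of 12 antenna genes 10 fell and 2 rose (10 and 2 adjusted over the list alone, median −5.69; camera adjusted p = 1.34e-06, 0.199 as adjusted p with an estimated correlation), LHCB5 by 6.05 ± 0.25, while LHCBM9 rose by 7.39 ± 1.41. Of 17 chlorophyll synthesis genes 14 fell and 1 rose (14 and 1 adjusted over the list alone, median −1.46; camera adjusted p = 3.87e-05, 0.250 as adjusted p with an estimated correlation), POR1, a protochlorophyllide reductase, by 3.06 ± 0.23. Of 12 fatty acid synthesis genes 9 fell and 1 rose (9 and 1 adjusted over the list alone, median −1.79; camera adjusted p = 5.41e-05, 0.118 as adjusted p with an estimated correlation), BCC1 by 3.96 ± 0.13. Of 11 Calvin cycle genes 8 fell (8 adjusted over the list alone, median −3.40, or −2.03 with single zeros set to missing; camera adjusted p = 2.75e-04, 0.0838 as adjusted p with an estimated correlation), PRK1 by 5.41 ± 0.35. Of 13 acetate genes 8 fell and 2 rose (8 and 2 adjusted over the list alone, median −2.01; camera adjusted p = 0.00287, 0.279 as adjusted p with an estimated correlation), ICL1 by 4.14 ± 0.19.

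Cell cycle, wall and phosphate transport genes fell as well at sulfur 48 hr. CYCB1, a B-type cyclin, fell by 4.94 ± 0.13, with 18 of 32 replication genes down and 3 up (19 and 3 adjusted over the list alone, median −1.01; camera adjusted p = 4.67e-05, 0.394 as adjusted p with an estimated correlation). PHC3, a pherophorin, fell by 3.84 ± 0.17, with 10 of 17 wall genes down and 2 up (10 and 2 adjusted over the list alone, median −2.81; camera adjusted p = 0.00487, 0.250 as adjusted p with an estimated correlation). PTA3 fell by 2.35 ± 0.17, with 7 of 11 phosphate genes down (7 adjusted over the list alone, median −1.26; camera adjusted p = 0.00320, 0.162 as adjusted p with an estimated correlation). IFT25 fell by 1.62 ± 0.19, with 10 of 26 transport genes down and 2 up (8 and 2 adjusted over the list alone, median −0.56; camera adjusted p = 0.0111, 0.510 as adjusted p with an estimated correlation). With quantile normalization 16 of these were down and 1 up (median −0.82). Of 38 cytosolic ribosomal protein genes 18 fell and 5 rose (18 and 5 adjusted over the list alone, median −0.42; camera adjusted p = 0.0255, 0.647 as adjusted p with an estimated correlation), and the direction turned with quantile normalization (12 up, 5 down, median 0.06). RPL24 fell by 1.23 ± 0.19 and RPS27e2 rose by 4.44 ± 0.16. Outside these lists NII1 rose by 3.54 ± 0.13, FUS1 by 2.17 ± 0.21 and SSS1, a starch synthase, by 2.01 ± 0.25. Heat shock genes had a median of −0.10 (0.44 with quantile normalization) and a mean of 1.00, and the list did not pass (adjusted p = 0.728). PSR1 did not change (0.06 ± 0.36, adjusted p = 0.898). SLT2 was listed at 0 and 2.18 FPKM at 0 hr and at 0 in both libraries at 48 hr, and NIT1 was below the filter.

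The order of events differed between groups. Carbon concentrating genes, which raise CO2 around rubisco, peaked at 30 min without nitrogen (9 of 10 up, median 3.75) and at 6 hr without sulfur (6 up, 1 down, median 3.14). LCIB, a low-CO2-inducible protein, rose by 6.38 ± 0.46 at nitrogen 30 min (limma adjusted p = 9.63e-07; 22.0 and 14.8 to 1448 and 1749 FPKM). Replication genes rose until 2 hr without nitrogen (29 of 31 up, median 1.36) and fell by 6 hr (23 down, 2 up), and without sulfur went from 22 up and 1 down at 2 hr to 30 down and 1 up at 6 hr. Proteasome genes turned at the same times, from 16 up at nitrogen 2 hr to 18 down at 6 hr and from 12 up at sulfur 2 hr to 19 down at 6 hr. Plastid ribosomal protein genes were lowest at 2 hr without nitrogen (median −3.95) and at 24 hr without sulfur (33 of 33 down). LHCB5 reached −10.39 ± 0.10 at nitrogen 24 hr (0.830 and 0.815 FPKM) and was unchanged until sulfur 2 hr (0.06 ± 0.25). LHCBM9 reached 9556 and 7388 FPKM at sulfur 6 hr. FUS1 rose by 4.83 ± 0.25 at nitrogen 6 hr and had not passed by sulfur 24 hr (0.454 and 0 FPKM). PSR1 rose by 2.73 ± 0.14 at nitrogen 30 min, and in the sulfur series passed only at 2 hr (1.55 ± 0.36, adjusted p = 0.00554).

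**Figure D2:**
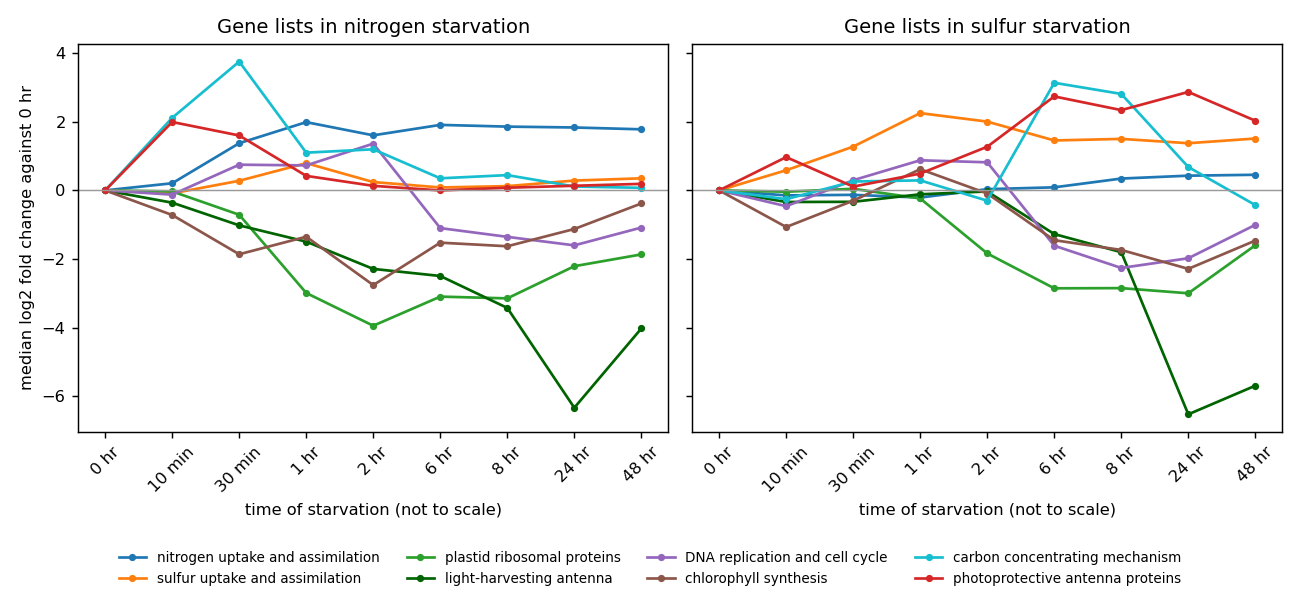
Median log2 fold change against 0 hr (y) of 8 gene lists by time (x, not to scale) of nitrogen (left) and sulfur starvation (right). Plastid ribosomal protein genes reached −3.95 at nitrogen 2 hr and −1.84 at sulfur 2 hr.

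**Figure D3:**
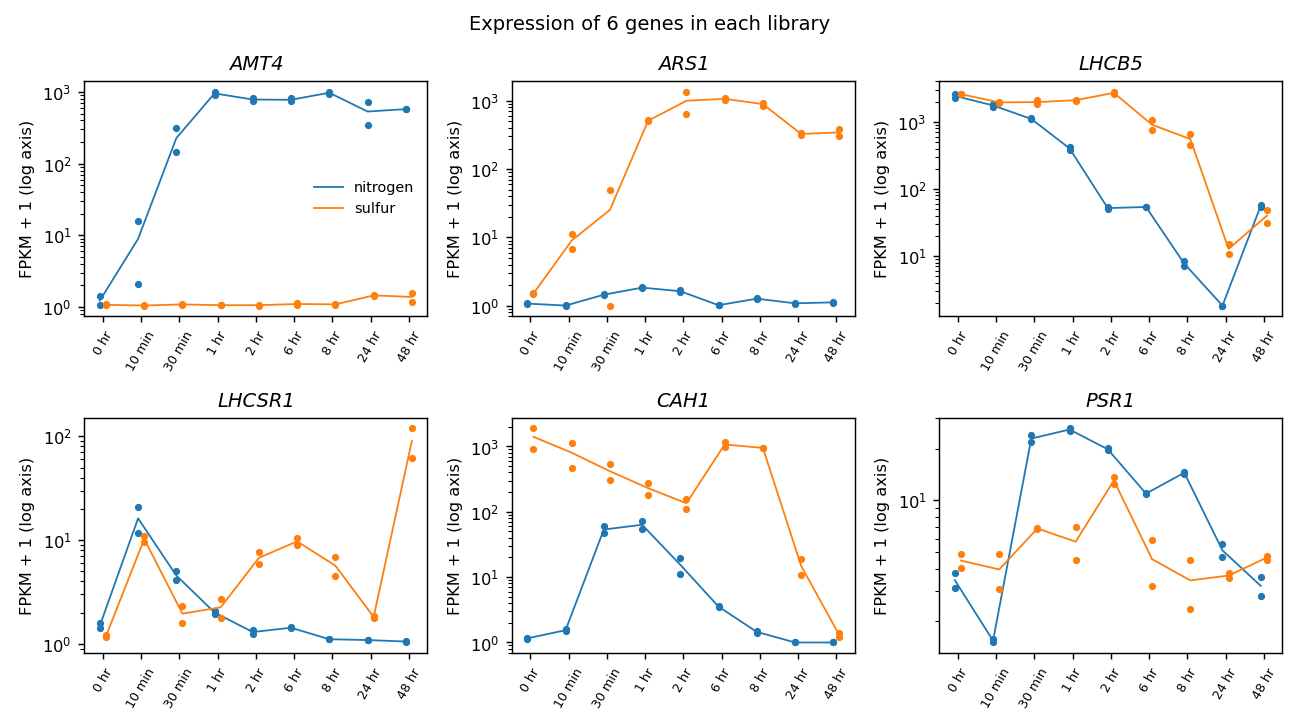
FPKM + 1 on a log axis (y) of AMT4, ARS1, LHCB5, LHCSR1, CAH1 and PSR1 by time (x), with a point per library and a line through the means of the nitrogen (blue) and sulfur (orange) series. LHCB5 reached 0.830 and 0.815 FPKM at nitrogen 24 hr.

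The responses to nitrogen and sulfur differed in many genes. At 1 hr 3677 genes had a higher and 1783 a lower change without nitrogen (interaction in limma, Benjamini-Hochberg, 14933 genes), and 2629 and 2425 with quantile normalization, which moved the median difference from 0.22 to 0.03. CAH1 rose without nitrogen and fell without sulfur (difference 8.32 ± 0.54, adjusted p = 2.16e-10), though its 0 hr levels differed (0.187 and 0.125 FPKM against 924 and 1887). SLT3 differed by 8.37 ± 0.88 and FLA10, the flagellar kinesin, by 1.75 ± 0.13. Of 17 chlorophyll synthesis genes 10 fell and 2 rose without nitrogen, and 11 rose without sulfur. The list was not tested for a difference between the series. Members that fell without nitrogen and rose without sulfur had differences of −5.13 ± 0.34 for GSA1, −4.65 ± 0.25 for CPX1, coproporphyrinogen oxidase, and −4.24 ± 0.22 for CHLI1. LHCBM9 (−8.60 ± 1.48) and Cre13.g585500 (−9.62 ± 0.27) rose only without sulfur. At 48 hr 2596 genes were higher and 2707 lower without nitrogen, against 1694 and 1968 with the compared times alone. POR1 rose by 0.86 without nitrogen and fell by 3.06 without sulfur (difference 3.92 ± 0.34, adjusted p = 1.53e-08), and RPS21, a cytosolic ribosomal protein, differed by 1.90 ± 0.38.

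The H3K4me3 series, a mark of active promoters, asked when chromatin changed most. At 1 hr without nitrogen 87 genes gained a promoter peak in both libraries and 0 lost it (no test was run on these counts), and 13498 genes had a peak in all 4. HSP22F (chr 14, 1396617–1398388, v5.3) and its neighbour HSP22E (1398588–1400061), small heat shock proteins, gained a peak and rose in RNA, by 3.82 ± 0.66 and 2.65 ± 0.22. LHCSR2 and LHCSR3 on chr 8, stress-related antenna proteins, gained a peak and rose by 0.50 ± 0.11 and 0.37 ± 0.13 (limma adjusted p = 0.00211 and 0.0295) while staying under 1 FPKM. AOC3, an amino acid carrier (0.62 ± 0.29, adjusted p = 0.0959), NAR1.6, a formate and nitrite transporter (0.28 ± 0.28, 0.413), and MMP9, a metalloproteinase (−0.21 ± 0.15, 0.258), gained a peak without passing in RNA. Of the 87, 51 were tested, 26 rose and 3 fell (median 0.42). That is 51.0% up, against 39.4% of 12754 tested genes that kept a peak (median 0.30), a difference that was not tested. With the upper 50% of each list by score 498 genes gained and 271 lost a peak. Between the 0 hr libraries 930 genes had a peak in library 2 only and 5 in library 1 only, and crossed splits of the same 4 libraries gave 106 gained and 2 lost, and 19 and 1. Leaving out 0 hr library 1 or 2 gave 89 gained and 24 lost, or 868 and 0, and leaving out 1 hr library 1 or 2 gave 155 and 2, or 111 and 25. Over time, 79.1% (Wilson 95% interval 78.5–79.7) and 84.5% of genes had a promoter peak at 0 hr, 84.2% and 85.1% at nitrogen 1 hr, and up to 81.9% at the other nitrogen times, each with 1 library, so no time stood outside the range of the 0 hr libraries except nitrogen 1 hr library 2. Against both 0 hr libraries, the sulfur 1 hr library gained a peak in 93 genes and lost it in 3, and the nitrogen libraries of times other than 1 hr gained it in 22–55 genes and lost it in 85–197. By size, 0 hr library 2, both nitrogen 1 hr libraries and the sulfur 1 hr library held 12821 to 13048 peaks. The lists of 0 hr library 1 and the other nitrogen times held 11487 to 12142 peaks. The 1 hr lists had Jaccard indices of 0.866 to 0.891 with 0 hr library 2, against 0.765 to 0.807 with library 1. A change at 1 hr and this split between lists, which parts the 0 hr libraries too, cannot be told apart.

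The other marks were compared at 0 hr, nitrogen 1 hr and sulfur 1 hr. At 0 hr genes with a promoter peak had higher RNA: median 4.82 FPKM with H3K4me3 against 0.127 without, 4.81 against 0.097 with H3K27ac, and 13.3 against 2.83 with RNA polymerase II (permutation over genes, p = 1e-05 each, the smallest possible). Genes with H3K27me3, a mark of silenced chromatin, were low (119 genes, 0.043 against 3.53 FPKM, permutation p = 4e-05), and so were genes with H3K4me2 (2.31 against 4.12, p = 1e-05). H3K27ac lists overlapped those of 0 hr with Jaccard indices of 0.812 to 0.856. H3K9me3, in other species a mark of silent chromatin, lay on 74.4% (Wilson 95% interval 73.8–75.1) of promoters at 0 hr, 59.1% (58.4–59.8) at nitrogen 1 hr and 16.4% at sulfur 1 hr, from 1 library each with 10575, 8120 and 2293 peaks. Of the bases in these lists 93.8%, 95.01% and 87.0% lay within an H3K4me3 list of the same time, and the 0 hr list had Jaccard indices of 0.814 and 0.715 with the 2 H3K4me3 0 hr lists (0.794 between these), so how far these lists measure H3K9me3 apart from H3K4me3 was not settled here. H3K27me3 was on 119, 130 and 237 promoters, and its Jaccard index with 0 hr was 0.649 for nitrogen and 0.0205 for sulfur. The sulfur 1 hr list kept 0 of the promoters marked at 0 hr, and 39.2% of its peaks lay at a transcription start, against 24.0% at 0 hr. Each list came from 1 library, so a change of the mark and a difference between lists cannot be told apart.

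Genes whose marks changed also changed in RNA at nitrogen 1 hr. Genes that gained H3K36me3, a mark of transcribed regions, rose in 65.8% of 774 tested (0.51 beyond genes with or without the mark at both times) and those that lost it fell in 45.4% of 482 (−0.72; stratified permutation p = 1e-05, adjusted p = 1.45e-05 for each). Genes that gained RNA polymerase II rose in 52.3% of 788 (0.39) and those that lost it fell in 34.2% of 1285 (−0.26; same p). Gained H3K27ac went with 65.2% up of 112 genes (0.48) and gained H3K9me3 with 67.1% up of 73 (1.31; same p). At sulfur 1 hr gained H3K36me3 went with 0.25 (363 genes), gained H3K27ac with 0.18 (181 genes), and gained RNA polymerase II with −0.09 (1939 genes; same p). Genes that kept RNA polymerase II at sulfur 1 hr had a median log2 fold change of −0.25, below the −0.08 of those that gained it and the −0.11 of those that lost it. Of those that kept it 27.3% fell, against 16.2% of those that lost it. Genes that lost H3K9me3 at sulfur 1 hr did not differ (9381 genes, 0.00, permutation p = 0.827), while at nitrogen 1 hr they were lower (2456 genes, −0.19, permutation adjusted p = 1.45e-05), though 889 rose and 513 fell. Lost H3K27ac went with −0.58 at nitrogen 1 hr (44 genes) and −0.22 at sulfur 1 hr (42 genes). At sulfur 1 hr lost H3K36me3 went with −0.08 (303 genes) and lost RNA polymerase II with −0.11 (537 genes). H3K27ac at 0 hr and nitrogen 1 hr and H3K36me3 at sulfur 1 hr had 2 libraries and the other lists 1, so genes and not libraries are the units of these tests.

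**Figure D4:**
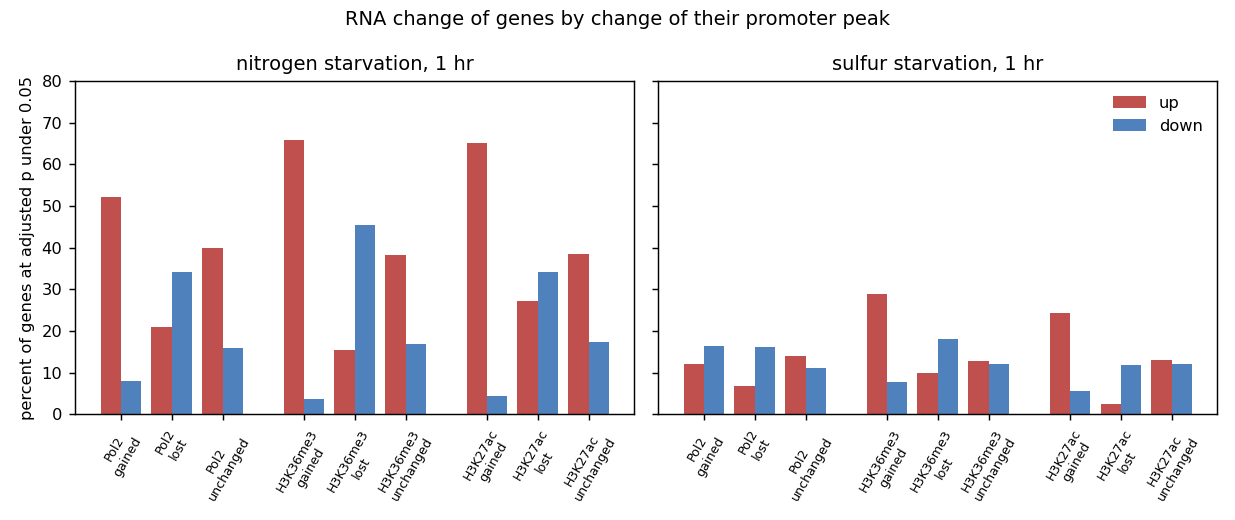
Percent of tested genes (y) that rose (red) or fell (blue) in RNA at 1 hr among genes that gained or lost, or were unchanged in, a promoter peak of RNA polymerase II, H3K36me3 or H3K27ac (x), without nitrogen (left) and sulfur (right). Of genes that gained H3K36me3, 65.8% rose without nitrogen and 28.9% without sulfur.

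The 16-state segmentation gives 9 states with H3K4me3, here called promoter states. The transcription start of 12449 genes (72.8%) lay in such a state at 0 hr, of 13317 (77.8%) at nitrogen 1 hr and of 13433 (78.5%) at sulfur 1 hr. There was 1 segmentation per condition, so these shares carry no spread between libraries. The 2 H3K4me3 lists at 0 hr alone gave promoter peaks in 79.1% and 84.5% of genes. Among genes that entered 1 at nitrogen 1 hr, GLN3, a glutamine synthetase, rose by 4.70 ± 0.30, XDH1, xanthine dehydrogenase, by 4.80 ± 0.12 and XUV1 by 5.82 ± 0.46, and at sulfur 1 hr ARS2 rose by 6.80 ± 0.20. SLT3 left these states at sulfur 1 hr and fell by 4.36 ± 0.53, while GCP3 left and rose by 0.92 ± 0.17. As a group, the 802 tested genes that entered at nitrogen 1 hr did not pass (0.06, stratified permutation p = 0.0603, adjusted p = 0.0908), nor did the 847 at sulfur 1 hr (0.03, p = 0.0681, adjusted p = 0.0908), while the 145 that left at nitrogen 1 hr were lower (−0.22, p = 0.00583, adjusted p = 0.0233) and the 75 that left at sulfur 1 hr, 6 up and 6 down, did not pass (−0.02, adjusted p = 0.548). With any promoter state within 500 bp the difference of genes that left at nitrogen 1 hr did not pass (−0.20, adjusted p = 0.394), that of genes that entered at sulfur 1 hr did (0.0695, adjusted p = 0.00376), and 2 that did not pass changed sign, entered at nitrogen 1 hr (−0.02, adjusted p = 0.829) and left at sulfur 1 hr (0.0058, adjusted p = 0.958). State 9, with H3K4me3, H3K27ac, H3K36me3 and H3K9me3, covered 5.45%, 5.43% and 0.874% of the genome at 0 hr, nitrogen 1 hr and sulfur 1 hr, and state 8, without H3K9me3, 0.0291%, 0.524% and 3.71%. The H3K9me3 list held 2293 peaks at sulfur 1 hr against 10575 at 0 hr. A change of state and a difference between these lists therefore cannot be told apart.

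PSR1 was profiled with antibodies A and B to ask which genes it binds during starvation. FMG1-B (g9144), the major glycoprotein of the flagellar membrane, was bound at all 5 conditions (peak chr 9, 291089–292541, v5.3), and its RNA rose by 1.27 ± 0.31 at nitrogen 30 min and 1.22 ± 0.19 at sulfur 6 hr (limma adjusted p = 0.00486 and 2.36e-04), with 0.79 at nitrogen 1 hr (0.0468) and no change passing at sulfur 1 hr (0.01, 0.991) and 2 hr (−0.19, 0.457). FMG1-A, the minor form, was bound at 4. SLT3 was bound at sulfur 1, 2 and 6 hr (peak chr 10, 3494703–3496520), when its RNA had fallen by 4.36, 4.58 and 4.20. AAH1, related to aromatic amino acid hydroxylases, was bound at sulfur 6 hr, when it rose by 3.48 ± 0.15. PFL1, pyruvate-formate lyase, was bound at sulfur 1 and 6 hr. PSR1's own promoter was bound with neither antibody. Bound by both antibodies were 25 genes at nitrogen 30 min, 18 at nitrogen 1 hr, and 33, 17 and 53 at sulfur 1, 2 and 6 hr, where 0.239 at nitrogen 30 min and at most 1.13 elsewhere would be shared by chance (Fisher's exact p from 2.00e-81 to 7.74e-33). In all 78 genes were bound, 46 of them at 1 condition only. At sulfur 1 hr 10 of 29 bound genes fell against 3.46 by chance (34.5% against 11.9%, odds ratio 3.90, Fisher's exact adjusted p = 0.0135), and at sulfur 6 hr 21 of 45 rose against 12.5 (46.7% against 27.9%, odds ratio 2.27, adjusted p = 0.0360). Neither passed with the upper 50% of peaks (adjusted p = 0.492 and 0.349), the first was lost with antibody A alone (1.54, adjusted p = 0.210) and the second among genes with an H3K4me3 promoter peak (2.08, adjusted p = 0.192). Without nitrogen none passed (lowest adjusted p = 0.229). Neighbouring genes can share a peak and were then counted as 2 bound genes, as for Cre16.g659700 and g15935 (peak chr 16, 2350626–2353390). Both rose at sulfur 6 hr (1.97 and 2.05), so bound genes are not independent units in these tests. Each antibody gave 1 library per condition.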

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

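The tests on single zeros and depth, on the H3K36me3 likeness of the 0 hr H3K9me3 list and on RNA polymerase II were written after the results were seen, and so was the limit that list lengths set on the test of H3K4me3 in the 0 hr H3K9me3 list, whose criterion was written before and was met. The others were written before.

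The responses differed between the series, with a signed log2 change that was higher in 3677 and lower in 1783 genes in nitrogen than in sulfur starvation at 1 hr, and in 2596 and 2707 at 48 hr. At 1 hr 353 of 14020 genes tested in both series rose without nitrogen and fell without sulfur, and 120 did the reverse. Among the named genes alone, those that moved in opposite directions at 1 hr, with the log2 difference of nitrogen minus sulfur, were CAH1 (8.32), SLT3 (8.37), PDC3 (3.31), FLA10 (1.75), IFT74 (1.67), IFT80 (1.47) and GSN1 (1.301), which rose without nitrogen and fell without sulfur. The reverse held for GSA1 (−5.13), CPX1 (−4.65), CHLI1 (−4.24), CHLI2 (−3.66), GUN4 (−4.30), PPX1 (−2.26), DLA2 (−2.47), PSBP4 (−1.81), LHCBM9 (−8.60) and Cre13.g585500 (−9.62). Some of the calls behind these directions were weak. At sulfur 1 hr those of PDC3 (−0.90 to −1.19), PPX1 (0.79 to 1.04) and PSBP4 (0.46 to 0.57) were lost without any 1 library of the 2 times, that of DLA2 without 0 hr library B (0.23) or 1 hr library A (0.29), and those of PPX1, PSBP4 and DLA2 with quantile normalization (0.76, 0.40 and 0.22). With the 2 times alone CAH1, DLA2, FLA10 and IFT80 did not pass at sulfur 1 hr, nor PDC3 and IFT74 at nitrogen 1 hr. Among the genes named at 48 hr, LHCBM7, listed at 0 at nitrogen 0 hr (13.60), CTH1 (3.19), POR1 (3.92) and RPS21 (1.90) were higher without nitrogen and HTB37 (−4.48), RPN3 (−1.06) and LHCBM9 (−8.41) without sulfur. The SE of the LHCBM7 difference was 2.32. This gene was above 0 at sulfur 0 hr, since it fell without sulfur (−5.20 ± 0.14), so its nitrogen 0 hr zeros may carry that difference. The highest number of peaks on the plastid and mitochondrial genomes in any list was 88, in an antibody A list at nitrogen 30 min, and those peaks were not analysed here.

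CAH1 and the carbon concentrating list differed between the series before starvation. At 0 hr the list's median was 1.45 log2 higher in the sulfur series, with the percentile of that difference at 100 among 10000 matched random lists. This speaks against a chance draw of unrelated genes only. The random lists drew genes independently, while members of this list moved together (estimated correlation 0.195 in the nitrogen and 0.382 in the sulfur series). The percentile therefore cannot speak on chance differences between cultures or libraries. The difference then ran from −1.46 at 10 min and −2.33 at 30 min to 5.82 at 6 hr, and only at 48 hr (0.57) did it lie within 1 of its start, but starvation itself moved the list (by 3.75 at nitrogen 30 min and 0.26 at sulfur 30 min) and each series had its own kit, so kit and culture at 0 hr cannot be told apart. A difference in CO2 supply between the cultures at 0 hr could leave such a pattern and was not measured. The opposite movement of CAH1 may therefore rest on its start and not on the nutrient.

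Single zeros, in genes at 5 FPKM or more in the other library, were more frequent in deeper libraries (Spearman's rho 0.6001 of depth and zeros over 36 libraries, permutation p = 2.2e-04; Pearson r 0.829, p = 2e-05). Without the 2 farthest libraries r was 0.455 (permutation p = 0.00895) and rho 0.527 (p = 0.0014), within nitrogen r 0.875 and rho 0.717, and within sulfur r 0.401 and rho 0.418 (permutation p = 0.0991 and 0.0852). A limit on fragments per gene would hit the highest genes, but the lost genes' median percentile was 36.5. Genes that share an assembled locus were 4.19 times as frequent among lost genes (49.4% against 11.8%, Fisher's exact p = 2.4e-62), so assignment of fragments to a neighbour could produce many of the zeros. RBCS1, MES1 and PRPL10 do not share a locus, so their zeros stay unexplained.

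H3K9me3 lay at promoters with H3K4me3, and the 0 hr list carries H3K36me3 in its peak names. Its Jaccard index with the H3K36me3 0 hr list was 0.532, under the lowest value among H3K36me3 lists (0.672), which speaks against both lists holding H3K36me3. An exchange of the 2 lists would leave this index unchanged, so it alone cannot decide on a swap. The list titled H3K36me3 at 0 hr overlapped every H3K36me3 1 hr list at 0.672 or more. It covered at least 50% of the body of 739 genes, against 464 to 591 genes in the H3K36me3 1 hr lists. For the 0 hr H3K9me3 list this was 184 genes, against 164 at nitrogen 1 hr and 27 at sulfur 1 hr. These values argue against a swap of these lists. With the 2 H3K4me3 0 hr lists the Jaccard index of the 0 hr H3K9me3 list was 0.814 and 0.715 (0.794 between these), but 93.8% of the 0 hr, 95.01% of the nitrogen 1 hr and 87.0% of the sulfur 1 hr H3K9me3 bases lay within H3K4me3. The fall of the index to 0.532 at nitrogen 1 hr met the criterion set beforehand for H3K4me3 in the 0 hr list, but list lengths, weighed only afterwards, allow at most 0.576 there and so fixed that outcome, and H3K4me3 in the 0 hr list and overlap of the marks cannot be told apart. Of the upper and lower 50% of 0 hr peaks by score 39.2% and 1.44% were met at sulfur 1 hr, so weaker enrichment may underlie the fall from 74.4% to 16.4% of promoters, which was not tested.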

How the results depend on the processing

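Of 280 values computed under alternatives for the main comparisons, 233 stayed the same, 5 were weaker, 6 stronger, 36 moved and 0 passed in the opposite direction, and the cause was not tested. A count within 1.5-fold of the main one was called the same, even where calls turned from mostly up to mostly down, as at nitrogen 48 hr. An emission of 0.8 gave the same 9 promoter states as 0.5, so the genes it selected could not differ. Signs did turn without passing, as for genes that entered a promoter state at nitrogen 1 hr (0.06 to −0.02), and with quantile normalization more genes fell than rose at nitrogen 48 hr (3938 and 3497, against 2885 and 4887). Beside these, 94 of 102 shares, 42 of 352 counts of list members and 21 of 35 counts of bound genes moved, and list medians that changed sign are named in the report. Of 3734 values of named genes 3488 stayed, 237 were weaker, 9 stronger and 0 reversed, and 78 of 373 named results had a weaker value somewhere. With the libraries of the compared times alone, genes up and down at sulfur 1 hr were 979 and 988 (1957 and 1735 in the full series) and genes higher without nitrogen at 48 hr 1694 (2596). Leaving out 1 library gave 989–1709 up and 977–1404 down at sulfur 1 hr. With quantile normalization 3972 genes rose at nitrogen 1 hr (5607). With a replicate block by letter, a pairing, 5634 rose and 2519 fell at nitrogen 1 hr, 4918 and 2920 at 48 hr, 1904 and 1717 at sulfur 1 hr, 5100 and 3602 at 48 hr, and the interaction gave 3711 and 1811, 2633 and 2732. No list passed camera with an estimated correlation (0, with 19 at an unadjusted p under 0.05).

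With the upper 50% of peaks by score H3K4me3 was gained in 498 genes and lost in 271 (87 and 0), and leaving out 1 library gave 89–868 and 0–25. The Jaccard indices with 0 hr in the upper 50%, nitrogen then sulfur, were 0.602 and 0.595 for H3K4me3, 0.588 and 0.608 for H3K27ac, 0.637 and 0.131 for H3K9me3, 0.648 and 0.0199 for H3K27me3, 0.610 and 0.633 for H3K36me3, and 0.314 and 0.406 for RNA polymerase II. With any promoter state within 500 bp, 55 genes left at nitrogen 1 hr (−0.20, adjusted p = 0.394), 24 left at sulfur 1 hr, and those that entered at sulfur 1 hr were at 0.0695 (adjusted p = 0.00376).

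PSR1 odds ratios changed with the definition of a bound gene. Over gene bodies they were 1.69 (adjusted p = 0.0357) for nitrogen 30 min down, 2.05 (0.0357) for sulfur 2 hr down and 0.432 (1.56e-04) for sulfur 6 hr down. With antibody A alone they were 1.54 (0.210) for sulfur 1 hr down and 0.611 (0.0221) for sulfur 6 hr down, and with antibody B alone 4.37 (0.0135) for sulfur 2 hr down. With the upper 50% of peaks they were 2.27 (0.492) for sulfur 1 hr down and 2.25 (0.349) for sulfur 6 hr up, and 2.08 (0.192) for the latter among genes with H3K4me3 at 0 hr. The number of bound genes ran from 7 to 232.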

Other observations

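The tests on RNA polymerase II were chosen after seeing results, and those on shared genes before.

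Nitrogen and sulfur starvation shared much of their late response. At 48 hr 2942 genes rose in both (1615 expected of 14020 tested in both, odds ratio 6.64) and 1774 fell in both (729 expected, odds ratio 8.51), among them LHCB5, PSBX, PSRP1 and PRK1, which fell, and NSG13, FUS1 and APG8, which rose. At 1 hr 1290 rose in both (748 expected, odds ratio 3.90) and 717 fell in both (300 expected, odds ratio 4.37; Fisher's exact p = 1.8e-160 and 1.8e-144). Genes that moved in opposite directions were fewer than by chance, 353 against 673 and 120 against 333 at 1 hr, and 332 against 1206 and 239 against 976 at 48 hr.

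The overlap of 2942 risers at 48 hr is in line with a common late program of slowed growth, and may also hold effects of washing and culture age that both series share. A washed series in complete medium would separate these. The turn of replication and proteasome genes between 2 and 6 hr in both series could reflect a clock of the cell cycle started by transfer, which the overlap of 1290 risers at 1 hr does not exclude. Sampling washed cells without starvation at 2 and 6 hr would test it.

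RNA polymerase II at promoters followed RNA without nitrogen and not in the same way without sulfur. Genes that gained a peak were 0.39 higher and those that lost it −0.26 without nitrogen, whereas without sulfur gained peaks went with −0.0919 and lost peaks with −0.11. The reference for these differences pooled genes with a peak at both times and genes with none. Genes that kept a peak had a median of 0.16 without nitrogen, between lost (−0.15) and gained (0.68). Without sulfur their median was −0.25, below both lost (−0.11) and gained (−0.08), so lost peaks did not go with a larger fall than kept peaks. Paused polymerase at promoters could give gained peaks without RNA, and the larger sulfur list (4385 peaks against 3143 at 0 hr) might instead reflect deeper or better enriched sequencing. A second polymerase library per condition would tell these apart.

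LHCBM9 rose to 9556 and 7388 FPKM at sulfur 6 hr while 9 of the 12 antenna genes fell, and it fell without nitrogen (difference −8.60 at 1 hr). An antenna protein poor in sulfur amino acids might replace others, which the overlap of 1774 genes that fell in both at 48 hr does not address. Counting cysteine and methionine in the encoded proteins would test it.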
